A study of Mus musculus with 16 samples.

How the data were processed

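Whole urinary bladders of 8 Balb/c mice were profiled on a 1-colour oligonucleotide array labelled with Cy5, from RNA extracted with Trizol. Per the labels, 4 male and 4 female mice received ketamine at 100 mg/kg/day for 20 weeks or normal saline (2 of each sex). The sample labels give no duration for saline. Sample titles carry a pair of numbers. No label says which number is the mouse, and the 2 mice per group of the study design fit either reading. The first was read as the mouse and the second as the array, which gives 2 arrays per mouse and 16 arrays. Arrays that share the first number differed less (median robust SD 0.122 log2 units) than arrays of a group that share the second (0.226).

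The deposited values are intensity on a linear scale after background subtraction, for 26423 probes per array, from -2.08 to 81430. On each array they were whole multiples of a step of 0.835 to 1.28 (100% of values within a tolerance of 0.01 steps), and 70 to 131 probes per array lay at or below 0. Scanner, background method and any scaling by the authors are not given in the sources used here. A symbol was given for 21876 probes and none for 4547. Chromosomal positions and a genome build are not given in the sources used here.

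Values at or below 0 were set to the lowest positive value (0.835), log2 values were taken and the arrays were quantile normalized. Each gene was represented by its probe with the highest mean. A gene was tested when it lay above the 40th percentile of all values (log2 5.99, an intensity of 63.6) in at least 4 of 16 arrays, which kept 13621 of 19084 genes. The arrays of a mouse were averaged, so that n counts mice. Where both mice of a group lay below this dim level, a fold is given as "at least", computed against that level.

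Group means of the 4 groups were fitted with limma 3.58.1 in R 4.3.3, with moderated variances (prior degrees of freedom 3.46, residual 4). Contrasts were ketamine minus saline in males, in females and averaged over both sexes, the female minus male difference of those responses, and female minus male in saline mice. The p-values were adjusted by Benjamini and Hochberg, and genes with an adjusted p under 0.05 were called. Intervals are 95% confidence intervals from the same fit, without adjustment for the number of genes. Their median width to each side was 0.49 log2 units in 1 sex, 0.35 over both sexes and 0.69 for the difference between the sexes. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

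Before the data were examined, 31 gene lists were fixed: urothelial (umbrella cell) differentiation, basal and squamous epithelium, contractile smooth muscle, extracellular matrix and fibrosis, inflammatory cytokines and prostaglandin synthesis, interferon response, MHC class II antigen presentation, macrophage and myeloid cells, mast cells, T and NK cells, B and plasma cells, endothelium, adipocytes, skeletal muscle, male accessory glands, uterus and oviduct, nerve and glia, blood cells, bladder neurotransmitter receptors and channels, glutamate receptors and other ketamine targets, drug metabolism, oxidative stress defence, apoptosis and p53 response, cell cycle, endoplasmic reticulum stress, immediate early and heat shock genes, oxidative phosphorylation, glycolysis and hypoxia, cholesterol synthesis, circadian clock, and sex-linked genes. The 30 with at least 4 measured members were tested. Camera from limma with a preset correlation of 0.01 compared each list with the other genes, and was repeated with an estimated correlation, under which 0 lists were called in any contrast. Fry tested whether a list moved in 1 direction or in either direction. For moves in 1 direction, fry called 0 lists in each ketamine contrast and 0 for the difference between the sexes. A list median is the median log2 change of its measured members, and counts "adjusted over the list alone" take the p-values of 1 list.

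Named genes followed a rule fixed at the same time: in each ketamine contrast and the saline sex contrast the 12 largest changes each way among genes past the threshold with the mice of the groups apart, and 5 each way for the difference between the sexes. Where fewer than 10 genes passed, the 10 with the smallest p were eligible as values that did not pass. Up to 4 members of each list with the smallest p, and a fixed set of bladder and sex-linked genes, could be named as well.

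Alternatives were other readings and uses of the arrays, other filters, probe choices, scalings, variance priors, models and thresholds, and each mouse left out in turn, where the lone mouse of a group is assumed to vary like the other groups. The planned quantile normalization equals the setting used. Added after the data were seen were an offset of 32, no further normalization, single lost spots left out, and sex over all 8 mice. The difference between mouse 1 and mouse 2 under saline was correlated across genes with that under ketamine, which gave 0.061 in males and 0.040 in females. The mice were therefore treated as unpaired, although these values cannot show that no pairing existed. The pipeline was tested on simulated data with 200 changed genes, and on a list shifted by 0.5 log2 units, which camera called with an adjusted p = 4.70e-17 and 0 other lists of 30. The simulated genes were drawn independently of each other. The simulation therefore cannot show how often camera wrongly calls lists of correlated genes, such as MHC class II genes (estimated correlation 0.389).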

Results

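Gene expression was measured in whole urinary bladders of Balb/c mice, an inbred laboratory strain. The mice had received ketamine daily for 20 weeks (100 mg/kg/day) or normal saline, for which the sample labels give no duration. Ketamine is a dissociative anaesthetic that blocks NMDA-type glutamate receptors, and long use is known to damage the bladder. The mice formed 4 groups of 2: male saline, male ketamine, female saline and female ketamine. As the titles were read, each mouse was measured on 2 arrays, which gave 16 arrays from 8 mice, and the number of mice limits the precision. Array medians of the deposited intensity ran from 99.0 to 168. The 4 female ketamine arrays held the highest of them, 146 to 168, against at most 126 on the other arrays. Of 19084 genes on the array, 13621 were bright enough to be tested, and values below are log2 intensities after quantile normalization, with each mouse the mean of its arrays.

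Female saline mouse 2 stood apart from the other mice. It lay at 48.6 on principal component 1 (30.8% of variance), where the other 7 mice lay between -16.8 and 7.69. On principal component 2 (20.8% of variance) the males and female saline mouse 2 lay between 9.62 and 17.0, and the other 3 females between -24.6 and -19.0. Eif2s3y, a Y-linked translation factor gene, averaged -0.03 in the saline females and 8.09 in the saline males, so the sex of that mouse was not in question.

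**Figure D1:**
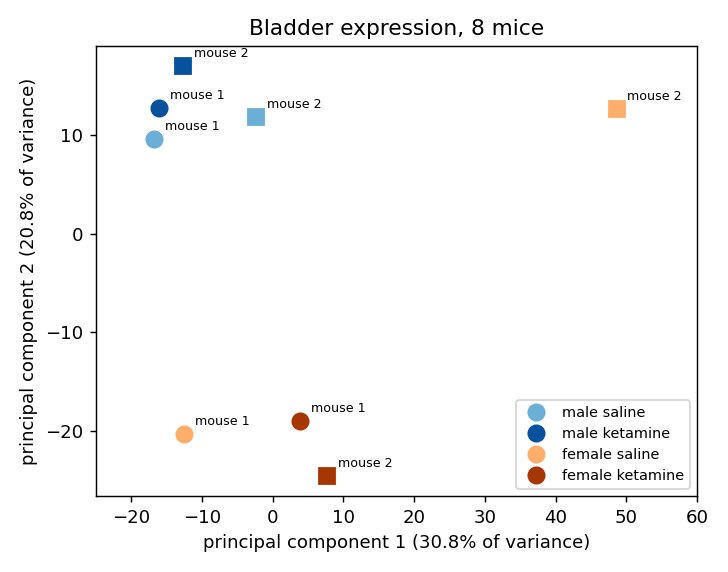
Principal components 1 and 2 (horizontal and vertical axis, in component score units) of the 13621 tested genes, with 1 point per mouse. Colours give the group, and circles and squares give mouse 1 and mouse 2 of a group. Female saline mouse 2 lies at 48.6 on component 1, and the other 7 mice lie between -16.8 and 7.69.

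In male mice, ketamine was compared with saline to find which bladder genes and pathways respond to long dosing in that sex (2 mice against 2). Immediate early and heat shock genes, which cells switch on quickly after stimulation or stress, stood higher as a group, with a median log2 change of 0.60 over 24 measured members, 15 positive and 9 negative. Fos, a transcription factor of the AP-1 complex (probe mMC013536), averaged 10.35 ± 0.46 (SD, n = 2) under saline and 12.47 ± 0.96 (SD, n = 2) under ketamine, a 4.35-fold difference. Its log2 change was 2.12 (95% confidence interval 1.11 to 3.13), and that of Egr1, another immediate early transcription factor, was 2.36 (1.04 to 3.69). Zfp36, which destabilises cytokine messengers, had a change of 0.71 (0.29 to 1.13), and Hspa1b, an inducible HSP70 chaperone, 0.66 (0.21 to 1.11). In each of these 4 genes both ketamine males lay above both saline males, and 3 members of the group passed adjusted over the list alone. Camera called the group (adjusted p = 1.87e-07), but the call did not hold in the other form of the test (adjusted p = 0.323 with an estimated correlation). The call held without each male mouse in turn, and the median was 0.29 without male ketamine mouse 2, where Egr1 had 1.56.

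Interferon response genes stood higher in the ketamine males, with 16 of 17 members positive and a median of 0.37 (adjusted p = 1.51e-06; adjusted p = 0.369 with an estimated correlation). Oas2, an antiviral oligoadenylate synthetase, had a log2 change of 0.54 (0.20 to 0.89), Isg15, a ubiquitin-like protein, 0.92 (0.12 to 1.72), and Irf7, a transcription factor of the interferon response, 0.65 (0.04 to 1.26), none of them past the test over all genes. The median was 0.24 without male saline mouse 2, and Irf7 had 0.36 without male ketamine mouse 2. Genes of endoplasmic reticulum stress were positive in 14 of 18 members, with a median of 0.22 (adjusted p = 0.00138; adjusted p = 0.323 with an estimated correlation). Hspa5, the main chaperone of that compartment, had a log2 change of 0.56 (0.17 to 0.96), and Pdia6 and Hsp90b1, which also help fold secreted proteins, had 0.45 and 0.38, with Pdia6 at 0.29 without male ketamine mouse 2. Without each male mouse in turn, the interferon and endoplasmic reticulum calls held.

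Genes of MHC class II antigen presentation stood lower in the ketamine males, with 8 of 9 members negative and a median of -0.36 (adjusted p = 0.00113; adjusted p = 0.444 with an estimated correlation). H2-Eb1, a class II beta chain, had a log2 change of -0.63 (-1.08 to -0.18), and Cd74, the invariant chain that escorts class II molecules, -1.02 (-2.11 to 0.07), or -0.56 without male ketamine mouse 1. The group call ended without male saline mouse 1 (median -0.15) and without male ketamine mouse 1 (median -0.29). Markers of nerve and glia were negative in 12 of 13 members, with a median of -0.37 (adjusted p = 0.00471; adjusted p = 0.444 with an estimated correlation). Uchl1, an enzyme abundant in neurons, stood at -0.48, S100b, a glial protein, at -0.37 and Mbp, a myelin protein, at -0.42. These lay nearer to 0, at -0.26 without male saline mouse 2, -0.19 without male saline mouse 1 and -0.20 without male ketamine mouse 2, and the call ended without male saline mouse 1 (median -0.16) and without male ketamine mouse 2 (median -0.21).

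Further groups passed the preset test in males with a higher adjusted p. Cell cycle genes had a median of 0.21 with 15 of 19 members positive (adjusted p = 0.00612; adjusted p = 0.630 with an estimated correlation), among them Top2a, a topoisomerase of dividing cells, at 0.80 (-0.15 to 1.75), or 0.34 without male ketamine mouse 2. The group median was 0.13 with 1 member near background set to its bound, 0.04 without male ketamine mouse 2, which ended the call, and 0.05 without male saline mouse 1. Apoptosis and p53 response genes had 0.21 with 15 of 20 positive (adjusted p = 0.0110; adjusted p = 0.444 with an estimated correlation), with the p53 target Trp53inp1 at 1.00 (0.29 to 1.71), or 0.55 without male ketamine mouse 2. That call ended without male saline mouse 2 (median 0.10) or male ketamine mouse 2 (0.11). Genes of inflammatory cytokines and prostaglandin synthesis had 0.25 with 13 of 21 positive (adjusted p = 0.0123; adjusted p = 0.323 with an estimated correlation). There Il1b, the cytokine interleukin 1 beta, stood at 0.45 (0.09 to 0.80) and Ptgs2, the inducible cyclooxygenase, at 0.53 (0.07 to 0.98), or 0.30 without male saline mouse 1, and the call ended without male ketamine mouse 1 (0.28). Endothelium markers had 0.14 with 11 of 14 positive (adjusted p = 0.0322; adjusted p = 0.737 with an estimated correlation), and the call ended without male saline mouse 1 (0.15) or male ketamine mouse 2 (0.01, where the test pointed down). Glutamate receptors and other ketamine targets had -0.26 with 7 of 11 negative (adjusted p = 0.0322; adjusted p = 0.369 with an estimated correlation), with the NMDA receptor subunit Grin2c at -0.69 (-1.30 to -0.08), and lost the call without male saline mouse 2 (-0.18), male ketamine mouse 1 (-0.42) or male ketamine mouse 2 (-0.11).

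No single gene passed in males: limma called 0 of 13621 genes (lowest adjusted p = 0.9997), with 310 at an unadjusted p under 0.05 against 681 expected by chance. That last count was 1071 without male ketamine mouse 1, 266 without male ketamine mouse 2, 173 and 219 without male saline mouse 1 and mouse 2, and 939 with array 1 only, so it lay on either side of chance. Among the 10 with the smallest p, Alas2, the first enzyme of haem synthesis in red cell precursors, had a log2 change of -1.20 (-1.75 to -0.64), and the cornified envelope genes Lce1k and Lce1d had -1.21 and -1.10. Across the alternatives Lce1k ran from -1.78 to -0.63 and Lce1d from -1.68 to -0.52. The cilium gene Cfap65 was at least 1.25-fold lower, Gpr180 at least 1.85-fold lower and Rtl5 at least 1.27-fold higher, each against a group near background. The fitted log2 change of Gpr180 ran from -1.96 to -0.17 across the alternatives, so not every setting reached its bound. Other fits gave 0 genes with mouse as a random block over all arrays, 1 with only these groups in the fit, and 16 when the 16 arrays were wrongly counted as independent. Leaving out 1 male mouse gave 1 or 2 genes: 1 without male saline mouse 1 or mouse 2 and 2 without male ketamine mouse 1 or mouse 2. With lost spots left out as well these were 0, 1, 2 and 3. The calls for the inflammatory, endothelium, nerve and glia, and glutamate groups also ended with array 1 of each mouse alone, and those for the inflammatory, endothelium, glutamate and cell cycle groups with the 60th percentile filter. Testing without a filter ended the endothelium and glutamate calls, and the mean of all probes the glutamate call.

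In female mice the same question was asked with separate controls (2 mice against 2). Markers of macrophages and myeloid cells stood lower under ketamine, with 13 of 16 members negative and a median log2 change of -0.45. Lyz1, the antibacterial enzyme lysozyme (probe mMC023485), averaged 10.07 ± 0.04 (SD, n = 2) under saline and 9.22 ± 0.14 (SD, n = 2) under ketamine, a 1.80-fold difference with a log2 change of -0.85 (-1.21 to -0.48). Aif1, a calcium-binding protein of macrophages, had -0.72 (-1.19 to -0.26), the chemokine receptor Cx3cr1 -0.86 (-1.52 to -0.20) and the integrin Itgam -0.61 (-1.11 to -0.12). In all 4 genes both ketamine females lay below both saline females, and 1 member passed adjusted over the list alone. Camera called the group (adjusted p = 1.71e-04, or adjusted p = 0.822 with an estimated correlation). Fry found change in either direction (adjusted p = 0.0176) but did not call a move in 1 direction (adjusted p = 0.376). The camera call ended without female saline mouse 1, at a median of -0.44 and with Itgam at -0.40.

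Other immune groups stood lower in the ketamine females as well. MHC class II genes were negative in 8 of 9 members, with a median of -0.48 (adjusted p = 0.00177; adjusted p = 0.822 with an estimated correlation). The class II chain genes H2-Eb1, H2-Aa and H2-Ab1 had log2 changes of -0.73 (-1.18 to -0.28), -0.50 (-0.91 to -0.09) and -0.55 (-1.14 to 0.03). T and NK cell markers were negative in 10 of 10 members, with a median of -0.37 (adjusted p = 0.00298; adjusted p = 0.822 with an estimated correlation), among them the T cell receptor component Cd3d at -0.77 and the granule protease Gzma at -0.88. Cd3d had -0.27 without female ketamine mouse 2, and Gzma -0.41 without female saline mouse 2. B and plasma cell markers were negative in 5 of 7 members, with a median of -0.57 (adjusted p = 0.00512; adjusted p = 0.822 with an estimated correlation), and 2 members passed adjusted over the list alone. Cd79b, a chain of the B cell receptor, had -1.26 (-2.10 to -0.41), and Mzb1, a chaperone of antibody-secreting cells, -0.76 (-1.23 to -0.28). The 3 calls ended without female saline mouse 1 (medians -0.41, -0.30 and -0.47), and the T and NK and the B and plasma cell calls also without female ketamine mouse 2 (-0.27 and -0.28) and with median centring. The 60th percentile filter left 2 T and NK members, too few to test, and the T and NK call ended without further normalization. Without further normalization the median of all genes was 0.41 higher in ketamine than in saline females, and the T and NK median (0.22), the B and plasma cell median (0.01) and the macrophage and MHC class II medians (-0.07 and -0.05) all lay below that shift.

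Endothelium and smooth muscle genes stood higher in the ketamine females. Endothelium markers were positive in 13 of 14 members, with a median of 0.20 (adjusted p = 0.00298; adjusted p = 0.849 with an estimated correlation), and Pecam1, the adhesion molecule CD31, had a change of 0.99 (0.17 to 1.81), or 0.39 without female saline mouse 2. Contractile smooth muscle genes were positive in 18 of 23 members, with a median of 0.12 (adjusted p = 0.0123; adjusted p = 0.907 with an estimated correlation), and Pln, the calcium pump regulator phospholamban, had 0.66 (0.12 to 1.19). The endothelium call ended without female saline mouse 1 (0.27) or mouse 2 (0.19) and without further normalization (0.63). For smooth muscle the call ended without female saline mouse 1 (0.04), with the 60th percentile filter and with median centring (-0.11, against a shift of -0.12 in all genes), and the direction turned without female ketamine mouse 2 (-0.03). Without further normalization the smooth muscle median was 0.42 against the shift of 0.41 in all genes, and its test pointed down.

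No single gene passed in females: limma called 0 of 13621 genes (lowest adjusted p = 0.909), with 566 at an unadjusted p under 0.05 against 681 expected by chance. That last count was 2704 without female saline mouse 1, 919 without female saline mouse 2, 500 and 249 without female ketamine mouse 1 and mouse 2, and 4053 without further normalization, where all genes were shifted by a median of 0.41. Edn1, the vasoconstrictor peptide endothelin 1, had a log2 change of 1.31 (0.67 to 1.94), Fbl, the methyltransferase fibrillarin of the nucleolus, 1.56 (0.89 to 2.22), and the adhesion molecule gene Cadm1 0.80 (0.43 to 1.17). Across the alternatives Fbl ran from 0.81 to 2.30. Skap1, an adaptor of T cell signalling, had -0.79 (-1.14 to -0.44), and the transcription factor gene Tbx1 was at least 1.96-fold lower. Other fits gave 0 genes with mouse as a random block, 0 with only these groups in the fit, 1 with an offset of 32, 1 with every probe tested, and 288 when the arrays were wrongly counted as independent. With 1 female mouse left out, the count depended on the mouse and on whether lost spots were left out as well. Removing lost spots raised the count without female saline mouse 1. It lowered the count without female saline mouse 2 or female ketamine mouse 2, so lost spots alone do not account for these counts. Without female saline mouse 1, the only saline female in the fit was mouse 2, which stood apart.

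Averaged over both sexes (4 mice against 4, each sex weighted equally), MHC class II genes were the group with the lowest p. Their median log2 change was -0.43, with 8 of 9 members negative, and the median of the group was lower in each ketamine mouse than in both saline mice of its sex. The margin was narrow in males. As a deviation from the mean of the 8 mice, the median was 0.034 in male ketamine mouse 2 and 0.058 in male saline mouse 2. H2-Eb1 (probe PH_mM_0015054) averaged 12.87 ± 0.29 and 12.91 ± 0.05 (SD, n = 2) in saline males and females and 12.24 ± 0.22 and 12.18 ± 0.01 (SD, n = 2) in ketamine males and females, a log2 change of -0.68 (standard error 0.14). H2-Aa had -0.43 (-0.72 to -0.14), H2-DMb1, which helps load peptide, -0.45 (-0.81 to -0.09) and H2-Ab1 -0.52 (-0.94 to -0.11), and 4 members passed adjusted over the list alone. Camera called the group (adjusted p = 2.22e-05; adjusted p = 0.406 with an estimated correlation) and kept the call without each of the 8 mice in turn, with medians from -0.50 to -0.35. Without further normalization the median was -0.24, against a shift of 0.19 in the median of all genes.

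**Figure D2:**
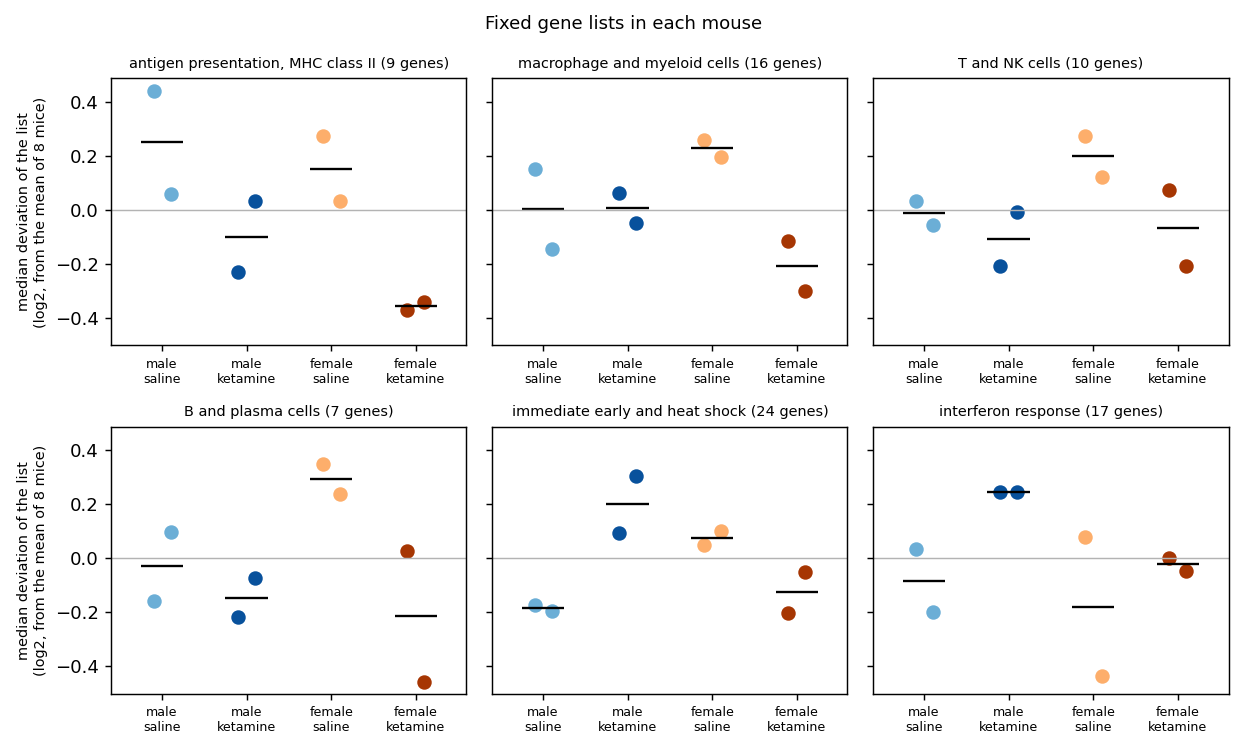
Median deviation of 6 gene groups from the mean of the 8 mice (vertical axis, log2), with 1 point per mouse, by group (horizontal axis), and the mean of 2 mice as a bar. The MHC class II median is lower in each ketamine mouse than in both saline mice of its sex, and immediate early and heat shock genes are higher in both ketamine males than in both saline males. The MHC class II margin is narrow between male ketamine mouse 2 (0.034) and male saline mouse 2 (0.058).

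Other immune cell groups had lower averages over both sexes, with wider variation between mice and sexes. T and NK cell markers were negative in 10 of 10 members, with a median of -0.24 (adjusted p = 9.05e-04; adjusted p = 0.406 with an estimated correlation), and the T cell adhesion molecule Cd2 had -0.40 (-0.74 to -0.06). Macrophage and myeloid markers were negative in 14 of 16 members, with a median of -0.18 (adjusted p = 0.0135; adjusted p = 0.406 with an estimated correlation). That average joined a median of -0.45 in females with one of 0.09 in males, where 10 of 16 were positive. Lyz1, which had -0.48 (-0.73 to -0.22) over both sexes, passed adjusted over the list alone. B and plasma cell markers had a median of -0.16 with 5 of 7 negative (adjusted p = 0.0135; adjusted p = 0.406 with an estimated correlation), and Cd79b at -1.01 (-1.60 to -0.41) and Mzb1 at -0.51 (-0.84 to -0.18) passed adjusted over the list alone. In males alone the T and NK median was -0.09 and the B and plasma cell median -0.06, and neither was called. The T and NK call ended without male ketamine mouse 1 (-0.19). The macrophage call ended without male saline mouse 1 (-0.09), male ketamine mouse 1 (-0.20), female saline mouse 1 (-0.20) or female ketamine mouse 2 (-0.12), and the B and plasma cell call without male ketamine mouse 1 (-0.26), female saline mouse 1 (-0.22) or female ketamine mouse 2 (-0.09). These medians were 0.02, 0.01 and 0.10 without further normalization, which is below the shift of 0.19 in the median of all genes.

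Groups with higher averages over both sexes included interferon response (median 0.22, 15 of 17 positive, adjusted p = 1.93e-04), endothelium (0.21, 13 of 14 positive, adjusted p = 1.93e-04), and immediate early and heat shock genes (0.23, 14 of 24 positive, adjusted p = 0.00176). Each had an adjusted p = 0.406 with an estimated correlation. The immediate early and heat shock average came from the males (0.60), since the female median was -0.12 with 16 of 24 negative. The interferon average came mostly from the males too (0.37), against 0.04 in females with 10 of 17 positive (adjusted p = 0.607). The heat shock members Hspa1a, Hspa1b and Dnajb1 had log2 changes of 0.55 (0.14 to 0.97), 0.45 (0.13 to 0.77) and 0.45 (0.12 to 0.79), and the vascular growth factor receptor Flt1 had 0.48 (0.05 to 0.92). The interferon call ended without female saline mouse 2 (0.06), the endothelium call without male ketamine mouse 2 (0.07), and the immediate early call without male ketamine mouse 2 (0.08) or female saline mouse 1 (0.14). Extracellular matrix and fibrosis genes had a median of 0.15 with 21 of 30 positive (adjusted p = 0.0154; adjusted p = 0.552 with an estimated correlation), and the fibrillar collagen genes Col1a2 and Col3a1 had 0.71 (0.09 to 1.33) and 0.75 (0.04 to 1.47). The matrix call ended without male saline mouse 1 (0.06), male ketamine mouse 2 (0.03), female saline mouse 2 (0.03) or female ketamine mouse 2 (0.13), and with median centring. Without male ketamine mouse 2, Hspa1a, Flt1, Col1a2 and Col3a1 had 0.36, 0.32, 0.46 and 0.43. Without further normalization the matrix and immediate early calls ended too, at medians of 0.32 and 0.40 against the shift of 0.19 in the median of all genes.

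Endoplasmic reticulum stress genes (median 0.12, 14 of 18 positive) and cell cycle genes (0.06, 15 of 19 positive) each had an adjusted p = 0.0135, and apoptosis and p53 response genes (0.15, 13 of 20 positive) an adjusted p = 0.0337. With an estimated correlation these became adjusted p = 0.406, adjusted p = 0.552 and adjusted p = 0.417. In females alone the medians were 0.07, 0.04 and 0.09, and these lists were not called there. The endoplasmic reticulum chaperone Hspa5 had a log2 change of 0.43 (0.15 to 0.71) and Top2a one of 0.75 (0.08 to 1.43). Across the alternatives Top2a ran from 0.48 to 1.03. The endoplasmic reticulum call ended without female saline mouse 1 (0.14) or female ketamine mouse 2 (0.11), and the cell cycle call without male ketamine mouse 2 (0.07), female saline mouse 1 (0.06) or female ketamine mouse 2 (0.05). The apoptosis call ended without male saline mouse 2 (0.12), male ketamine mouse 2 (0.08), female saline mouse 2 (0.02) or female ketamine mouse 1 (0.13). With mouse as a random block the endoplasmic reticulum and apoptosis calls ended, with median centring the endoplasmic reticulum call, with every probe tested the apoptosis call, and with the 60th percentile filter the cell cycle call. Without further normalization the endoplasmic reticulum and apoptosis calls ended.

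Single genes of the urothelium and of the bladder muscle, fixed in advance, did not pass the test over both sexes. Upk1a, Upk2 and Upk3a encode uroplakins, the plaque proteins of umbrella cells, and had log2 changes over both sexes of -0.02 (-0.26 to 0.21), -0.13 (-0.43 to 0.17) and -0.04 (-0.27 to 0.20). The keratin genes Krt5, Krt14 and Krt20 of basal and umbrella cells had -0.03 (-0.35 to 0.28), 0.08 (-0.42 to 0.58) and 0.06 (-0.23 to 0.36). Acta2, Myh11 and Des, which encode the actin, myosin and desmin of smooth muscle, had 0.00 (-0.26 to 0.26), -0.01 (-0.25 to 0.23) and -0.17 (-0.53 to 0.18). The Acta2 value comes from a very bright probe (mean log2 15.51), and a dimmer one (13.79) had 0.22 in males and 0.62 in females. Tgfb1, a driver of fibrosis, had -0.08 (-0.35 to 0.20). Ptgs2 had 0.43 (0.11 to 0.75), higher in both ketamine mice of each sex, with an adjusted p = 0.978 in limma. Among receptors, the muscarinic receptor gene Chrm3 had 0.37 (-0.44 to 1.17), the purine receptor gene P2rx1 0.06 (-0.33 to 0.46), and Chrm2 -0.64 (-3.51 to 2.23), an interval too wide to read. Col1a1 and Nos2 fell below the brightness filter, and Grin1 and Ddx3y were not analysed here because no named probe carries them.

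**Figure D3:**
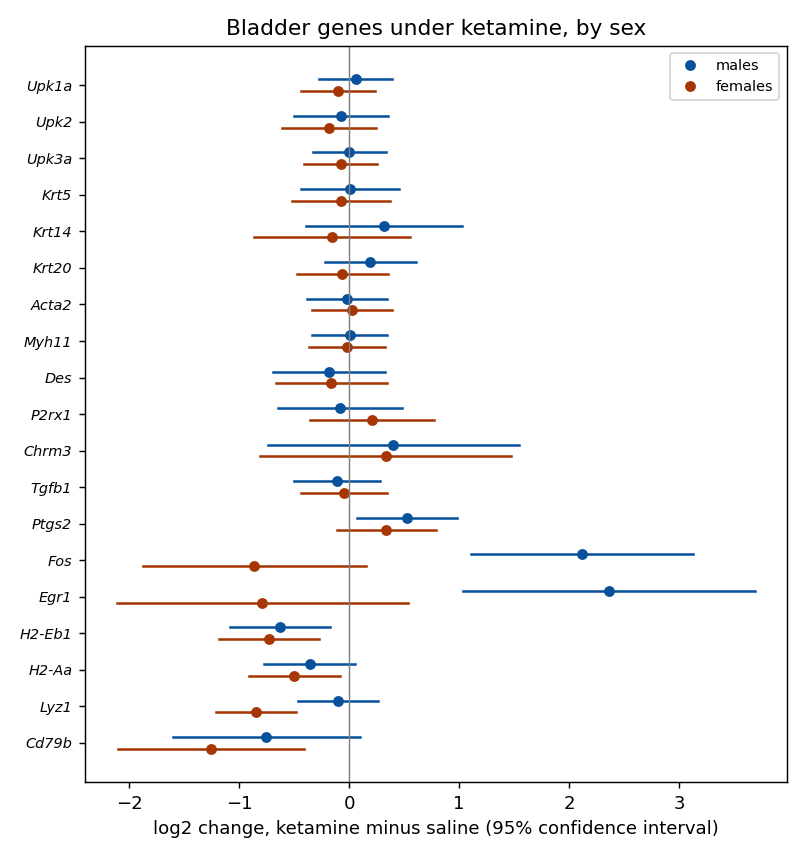
Log2 change under ketamine (horizontal axis) of 19 named bladder genes (vertical axis) in males and females, with 95% confidence intervals from limma. Intervals of the uroplakin genes Upk1a, Upk2 and Upk3a and of the muscle genes Acta2 and Myh11 span 0 in both sexes, and Fos stands at 2.12 in males. Without further normalization, which shifts all genes in females by a median of 0.41, the female values of Upk1a, Upk2, Upk3a, Krt5, Krt14, Krt20, Myh11, Des and Tgfb1 turn positive, and with median centring (a shift of -0.12) those of Acta2 and P2rx1 turn negative. Relative to these shifts, Tgfb1 and Acta2 turn and the other 9 genes keep their sign. In males, Upk3a and Acta2 turn with median centring and Myh11 turns without further normalization, each at less than 0.05.

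The remaining groups were not called over both sexes. Umbrella cell differentiation genes had a median of -0.01 (adjusted p = 0.804), with a mean of -0.13 and an upward test statistic, because Krt8 was lost on 1 array of each of 2 ketamine mice. Basal and squamous epithelium had -0.03 (adjusted p = 0.997), contractile smooth muscle 0.06 (adjusted p = 0.147), inflammatory cytokines and prostaglandin synthesis 0.07 (adjusted p = 0.234) and mast cells 0.01 (adjusted p = 0.720). Adipocytes had 0.09 (adjusted p = 0.458), skeletal muscle -0.10 (adjusted p = 0.391), male accessory glands -0.03 (adjusted p = 0.674), uterus and oviduct 0.01 (adjusted p = 0.921), and nerve and glia -0.16 (adjusted p = 0.354). Bladder neurotransmitter receptors and channels had 0.01 (adjusted p = 0.804), glutamate receptors and other ketamine targets -0.15 (adjusted p = 0.212), drug metabolism 0.07 (adjusted p = 0.119) and oxidative stress defence 0.06 (adjusted p = 0.234). Nqo1, an antioxidant enzyme of that group, had a log2 change of 0.54 (0.15 to 0.92). Oxidative phosphorylation had 0.05 (adjusted p = 0.391), glycolysis and hypoxia 0.02 (adjusted p = 0.321), cholesterol synthesis -0.04 (adjusted p = 0.493), the circadian clock 0.05 (adjusted p = 0.371) and the sex-linked genes 0.09 (adjusted p = 0.128). Blood cell genes had 3 measured members and were not tested.

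Over both sexes limma called 0 of 13621 genes (lowest adjusted p = 0.978), with 404 at an unadjusted p under 0.05 against 681 expected by chance. That last count was 1977 without female saline mouse 1, 1122 without male ketamine mouse 1, 675 without female saline mouse 2, 221 to 284 without each of the other 5 mice, and 1614 without further normalization. Other fits gave 0 genes with mouse as a random block, 0 with an additive model of sex and treatment, 1 with every probe tested and 21 when arrays were wrongly counted as independent. Without female saline mouse 2 the count was 11, without female saline mouse 1 it was 5, without female ketamine mouse 2 it was 2, and without male saline mouse 2, male ketamine mouse 1 or female ketamine mouse 1 it was 1. With lost spots left out as well these were 1, 2 and 0, and 1, 0 and 0. In simulated data, 86.9% of 2-fold changes and 99.0% of 4-fold changes were recovered over both sexes, and 44.2% and 95.8% in 1 sex. Noise there was normal and independent between genes, at limma's moderated variances, with 200 genes changed 2-, 4- or 8-fold. Mice that stand apart were thus absent, and the shares hold for that number and size of changes only. They do not show that 2-fold changes would have been found here.

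The male and female responses were then compared with each other, which is needed before a change can be placed in 1 sex. Immediate early and heat shock genes differed in their response, with a median female minus male difference of -0.31 and 18 of 24 members negative. Fos had a log2 change of 2.12 in males and -0.86 in females, a difference of -2.98 (-4.41 to -1.55), and Egr1 a difference of -3.15 (-5.03 to -1.28), and 1 member passed adjusted over the list alone. Camera called the difference (adjusted p = 1.66e-04; adjusted p = 0.598 with an estimated correlation), and the call held without each of the 8 mice in turn. Without male ketamine mouse 1 the median was -0.54, with median centring -0.63 and without further normalization -0.04, against shifts of -0.17 and 0.42 in the median of all genes for these scalings. Macrophage and myeloid markers also differed, with a median of -0.52 and 12 of 16 negative (adjusted p = 1.66e-04; adjusted p = 0.598 with an estimated correlation). Cx3cr1 had a difference of -1.25 (-2.18 to -0.32) and Aif1 one of -0.90 (-1.56 to -0.24), and the call ended without female saline mouse 1 (-0.60), while the median was -0.30 without male saline mouse 2.

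Other groups passed with a higher adjusted p. Nerve and glia had a median difference of 0.38 with 11 of 13 positive (adjusted p = 0.0256; adjusted p = 0.797 with an estimated correlation), contractile smooth muscle 0.13 with 18 of 23 positive (adjusted p = 0.0332; adjusted p = 0.906 with an estimated correlation), and interferon response -0.09 with 10 of 17 negative (adjusted p = 0.0412; adjusted p = 0.871 with an estimated correlation). With array 1 only these 3 calls ended, as did the smooth muscle call with the 60th percentile filter, the interferon call with median centring, and the nerve and glia and smooth muscle calls without further normalization. Mbp had a difference of 1.18 (0.28 to 2.08), Pln one of 0.82 (0.06 to 1.57) and Isg15 one of -1.27 (-2.40 to -0.15), with Pln at 0.49 without male saline mouse 2 and Isg15 at -0.70 without female saline mouse 1. The nerve and glia call ended without male saline mouse 1 (0.28), male ketamine mouse 1 (0.61), male ketamine mouse 2 (0.42), female saline mouse 2 (0.21) or female ketamine mouse 1 (0.43). The smooth muscle call ended without male saline mouse 2 (0.06), male ketamine mouse 1 (0.11), female saline mouse 1 (0.08) or female ketamine mouse 2 (-0.03, the opposite direction), and with median centring (-0.14, against a shift of -0.17 in all genes). The interferon call ended without male saline mouse 2 (-0.04), male ketamine mouse 1 (-0.26), male ketamine mouse 2 (-0.16), female saline mouse 1 (0.15, the opposite direction) or female ketamine mouse 1 (-0.08).

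For single genes the difference between the sexes passed in 0 of 13621 in limma (lowest adjusted p = 0.993), with 472 at an unadjusted p under 0.05. Other fits gave 2 genes with mouse as a random block, 1 with every probe tested and 144 when arrays were wrongly counted as independent. The count at an unadjusted p under 0.05 was 1972 without female saline mouse 1, 849 without female saline mouse 2, 762 without male ketamine mouse 1, 236 to 516 without each of the other 5 mice, and 2338 without further normalization. Btk, a kinase of B cell signalling, had a difference of -1.75 (-2.59 to -0.90). The guidance receptor gene Nrp1 had one of 1.07 (0.56 to 1.59), with -0.48 in males and 0.59 in females, where another probe had 0.38 and 0.73. Without female saline mouse 2 the count was 7, without female saline mouse 1 it was 4, and without male saline mouse 2, male ketamine mouse 1 or either female ketamine mouse it was 1. With lost spots left out as well these were 1 and 2, then 1, 0 and 0, and without male ketamine mouse 2 it was 3. Across the 13621 genes, the log2 changes of males and females correlated at Pearson -0.04 and Spearman 0.02, and 51.8% had the same sign (genes are not independent replicates). At an unadjusted p under 0.05 in both sexes stood 35 genes, against 12.9 expected if the 2 sets were independent, and 10 of the 35 had the same sign. Both tests use the same variance of a gene, so this overlap does not show a shared response. The Pearson correlation was 0.11 without male ketamine mouse 1 and -0.19 without male ketamine mouse 2.

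Saline females and saline males were compared to check the sex labels and to give the background of sex (2 mice against 2). Sfrp4, a secreted Wnt inhibitor (probe PH_mM_0004579), was 4.39-fold higher in females, at 9.28 ± 0.22 (SD, n = 2) against 7.15 ± 0.31 (SD, n = 2) in males, a log2 difference of 2.14 (1.65 to 2.62, adjusted p = 0.0311 in limma). Sult1e1, the oestrogen sulfotransferase, was at least 11.9-fold lower in females (adjusted p = 5.41e-06). The Y-linked genes Eif2s3y and Kdm5d were at least 4.29-fold (adjusted p = 5.41e-06) and at least 3.55-fold lower (adjusted p = 2.19e-04), and Y-linked Uty, at 6.09 and 5.71 in the saline females, on either side of the dim level, had a fitted log2 difference of -3.39 (-3.84 to -2.93, adjusted p = 8.98e-04). Padi3, a peptidylarginine deiminase, was at least 2.07-fold lower (adjusted p = 0.0314). Xist, the RNA of X inactivation, had 1.71 (0.23 to 3.19, adjusted p = 0.867), or 0.62 without female saline mouse 2. The other 6 genes, 1 higher and 5 lower in females, were all that limma called, with 700 at an unadjusted p under 0.05 (2768 without female saline mouse 1, 940 without female saline mouse 2, 332 and 419 without male saline mouse 1 and mouse 2). The count of called genes was 72 with mouse as a random block, 3 with only these groups in the fit, 64 without female saline mouse 1 and 18 without female saline mouse 2, the last 2 being 69 and 8 with lost spots left out as well.

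Adipocyte markers stood higher in saline females, with 10 of 11 positive and a median log2 difference of 0.47 (adjusted p = 0.00201; adjusted p = 0.768 with an estimated correlation). Pck1, the enzyme phosphoenolpyruvate carboxykinase, had 3.72 (2.41 to 5.03) and passed adjusted over the list alone, and Scd1, a fatty acid desaturase, had 1.09 (0.34 to 1.83), or 0.62 without male saline mouse 1. The adipocyte call ended without female saline mouse 1 (0.22), and the median was 0.93 without female saline mouse 2, 0.88 without male saline mouse 2 and 0.25 without male saline mouse 1. The sex-linked genes had a median of 0.18 but a mean of -1.55 and a downward test (adjusted p = 0.00201; adjusted p = 0.504 with an estimated correlation), since 3 Y-linked members were lower by far more than the X-linked members differed, and the call ended without female saline mouse 1 (-0.11). Immediate early and heat shock genes had 0.26 with 15 of 24 positive (adjusted p = 0.0134; adjusted p = 0.768 with an estimated correlation), and 2 passed adjusted over the list alone, with Hspa1b at 1.19 (0.74 to 1.64) and Hspa1a at 1.37 (0.78 to 1.96).

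Lower in saline females were markers of nerve and glia (median -0.31, 10 of 13 negative, adjusted p = 0.0234), endothelium (-0.16, 14 of 14 negative, adjusted p = 0.0302) and extracellular matrix (-0.23, 23 of 30 negative, adjusted p = 0.0459). With an estimated correlation these became adjusted p = 0.768, adjusted p = 0.768 and adjusted p = 0.854. Ccn2, a matrix-associated growth factor, had -1.53 (-2.21 to -0.84) and passed adjusted over the list alone, whereas the matrix protease gene Mmp3 had 1.20 (0.37 to 2.04). Without female saline mouse 2, which stood apart, the nerve and glia median was -0.13, the endothelium median -0.15 and the matrix median -0.02, and all 3 calls ended. The immediate early call ended without female saline mouse 1 (0.30) or mouse 2 (0.22), the endothelium call also without female saline mouse 1 (-0.14) or male saline mouse 2 (-0.13), the nerve and glia call without male saline mouse 1 (-0.37) and the matrix call without male saline mouse 2 (-0.08). The nerve and glia, endothelium and matrix calls also ended without further normalization, the first 2 with the 60th percentile filter, the endothelium call with mouse as a random block or array 2 only, and the matrix call with median centring, no filter, the mean of probes or mouse number as a replicate block.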

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

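Tests of a lower share of leukocytes, and of a failed array and of single probes in female saline mouse 2, were chosen after the results were seen. With 4 mice per comparison, 96 sets of values were examined for a mouse far from the other 3, and 3 were found, where chance gives 4.8 (1 in 20).

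Female saline mouse 1 lay at -20.4 on principal component 2, against 9.62 to 12.7 in the other saline mice. Both ketamine females lay near it (-19.0 and -24.6), so on this component female saline mouse 2 (12.7) was the mouse away from its sex. The mast cell median was 0.168 in male saline mouse 1 and -0.0779 to -0.0460 in the other saline mice. For glutamate receptors and other ketamine targets, male ketamine mouse 1 had a median of -0.00230 and the other ketamine mice -0.0850 to -0.0762. The female minus male response differed by the camera test for contractile smooth muscle (0.130), interferon response (-0.0895), macrophage and myeloid cells (-0.524), nerve and glia (0.385), and immediate early and heat shock genes (-0.309). None of these 5 differences was called with an estimated correlation.

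Lower MHC class II genes under ketamine were weighed first. Dependence on 1 mouse was argued against for the camera call over both sexes with the preset correlation. Its highest adjusted p over the 8 mice left out in turn was 0.0232, and the median stayed negative (-0.504 to -0.348). That test compares genes with other genes, so it does not measure the spread between mice. With an estimated correlation, camera did not call the list with all 8 mice (adjusted p = 0.406). A lower share of all leukocytes could account for the females, where the highest median of the macrophage, T and NK, and B and plasma cell lists over the mice left out was -0.274. In males the macrophage median was 0.0863 (-0.0537 to 0.194 over the mice left out). The MHC class II median stayed between -0.508 and -0.148 there. These values argue against a fall of macrophage markers in males as large as that of MHC class II genes. The ranges come from 2 mice per group and are not confidence intervals, so a smaller fall in leukocytes is not excluded. T and NK cells (-0.0905, -0.236 to -0.0420) and B and plasma cells (-0.0621, -0.215 to 0.0629) overlapped the MHC class II range in males. A lower share of lymphocytes alone therefore stays open there. Chance was not excluded: 2 of the 34 splits of the 8 mice gave a median as far from 0 as the real size of 0.429, the highest other being 0.443 (0.365 among the 18 with 2 mice of each sex on each side), and an effect of ketamine on antigen presentation stays open.

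Female saline mouse 2 lay apart from the other mice, with 304 of 9310 bright genes low in it against 19 to 72 in the others. A single failed array was argued against, because the deviations of its 2 arrays correlated at 0.917 across genes, which are not independent replicates. That agreement does not bear on faults common to both arrays. Their medians of deposited intensity, 99.8 and 99.0, were the lowest of the 16 arrays. Loss of signal at single probes stays open: other probes of 17 low genes had a median deviation of -0.887 (bootstrap interval -1.47 to -0.0859), where the first probes had -1.41. A different make-up of the tissue piece stays open too, with 5.33% of 150 cell type markers low against 3.23% of other genes, a ratio of 1.65 (interval of the odds ratio 0.708 to 3.46). By list, the median deviation of this mouse from the others ran from -0.737 (nerve and glia) to 0.239 (macrophage and myeloid cells). Extracellular matrix and fibrosis genes lay at -0.405 and interferon response genes at -0.389. No other biological explanation was tested, since no group in the design sets this mouse apart.

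For higher immediate early and heat shock genes in ketamine males, the camera call with the preset correlation did not rest on 1 mouse. Its highest adjusted p over the mice left out in turn was 1.31e-04, and the median stayed positive (0.285 to 0.814). That test compares genes with other genes, so it does not measure the spread between mice. With an estimated correlation, camera did not call these genes with all mice in the fit (adjusted p = 0.323). Handling at the time of death could contribute, because these genes respond within minutes and no label records it. Mice of 1 group differed in these genes by a median of 0.350, against 0.214 in genes of like level. The ratio, taken gene by gene, had a median of 1.55 (bootstrap interval 1.25 to 2.83). That is consistent with handling as a source, and an effect of ketamine in males stays open as well.

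Other splits of the 8 mice into 4 and 4 were fitted with sex as a term. For ketamine over both sexes, 34 of 34 splits had to give at least the real count of 0 genes (highest other 1), so this comparison says nothing about chance. At an unadjusted p under 0.05, 20 of 34 splits gave at least the real count of 448, and the highest other, 2251, set male saline mice 1 and 2, male ketamine mouse 1 and female saline mouse 2 against the rest, which points to a structure of the samples. For called lists, with the preset correlation, the other splits gave a median of 5, so groupings other than by treatment also gave list calls. Of 34 splits, 1 reached the real count of 11 and the highest other gave 10. Among the 18 splits with 2 mice of each sex on each side, as in the real one, 1 reached it and the highest other gave 10, and 18 are too few for a share under 0.05, so the case against chance rests on unbalanced splits. With treatment in place of sex as the term, other splits reached 11 lists, and with an estimated correlation the real count was 0. For sex, with treatment as a term, only the real split of 34 reached the count of 27 genes, and the highest other gave 1. Y-linked genes must differ in that split, so the outcome was largely fixed beforehand and does not exclude chance for the other genes. Of the 18 splits with 2 mice of each treatment on each side, 1 reached 27 and the highest other gave 0. These 18 are likewise too few on their own.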

How the results depend on the processing

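The comparison of the sexes over all 8 mice, the offset of 32, no further normalization and the removal of lost spots were chosen after the data were seen. Across alternatives, list medians kept direction and side of the threshold in 749 cases, lost the call in 165 and reversed in 5. Gene counts stayed within 1.5 times in 93 cases and moved in 56, list counts in 114 and 29. For single named genes 6455 values stayed on the same side of the threshold, 298 became calls and 59 lost a call. Most of the 6455 were not called to begin with, as 0 genes passed in the ketamine contrasts. A turn of sign was counted only for called genes. Krt5 over both sexes, for example, kept its sign in 19 of 25 settings. Moderation with a trend or robustly, mouse number as a replicate block, the mean of probes, lost spots left out, and a 2-fold threshold beside the adjusted p moved no gene count beyond 1.5 times with all 8 mice in the fit. Signal over background limits the dim genes, whose folds are bounds. Unless construction shows it, the cause was not tested.

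Counts below are in the order males, females, both sexes, difference of responses, sex in saline, sex over all 8 mice. With 16 arrays counted as independent they were 16, 288, 21, 144, 509 and 1616, and with the second title number read as the mouse 2543, 4872, 4288, 3907, 5078 and 6452, as follows if each such mouse averages arrays of different mice. At an unadjusted p under 0.05 and 2-fold they were 34, 55, 15, 150, 134 and 77. With mouse as a random block the last 3 were 2, 72 and 179, with 5 lists for sex over all mice. Every probe gave 1 gene in females, 1 over both sexes and 1 for the difference; an offset of 32 gave 1 in females; only the 2 groups compared gave 1 in males and 3 for sex in saline; and for sex over all mice median centring gave 29 and an additive model 27. With an estimated correlation 0 lists were called in any of the 6 contrasts. Array 1 only gave 6 lists in males, 2 for the difference and 2 for sex over all mice, array 2 only 6 for the last, median centring 3 in females, no filter 0 for sex over all mice, and the 60th percentile filter 6 in males and 2 for sex over all mice. No further normalization gave 9 lists for the difference and 4 for sex over all mice.

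Without each mouse in turn the gene counts ranged from 1 to 2, 0 to 17, 0 to 11, 0 to 7, 5 to 64 and 7 to 94, and the list counts from 7 to 11, 0 to 8, 6 to 13, 2 to 7, 2 to 8 and 0 to 7. The counts 17, 64 and 94 came without female saline mouse 1, and 11 and 7 (difference) without female saline mouse 2. With lost spots left out as well, these 5 counts were 73, 69, 144, 1 and 1. The correlation of male and female responses ranged from -0.189 to 0.109. Reversed were contractile smooth muscle in females without further normalization (0.417 against a shift of 0.41 in all genes, with the test pointing down) and without female ketamine mouse 2 (-0.0323, range to 0.452 over the mice left out), the same list for the difference without female ketamine mouse 2 (-0.0281, range to 0.396), endothelium in males without male ketamine mouse 2 (0.0125 with the test pointing down, range to 0.228) and interferon response for the difference without female saline mouse 1 (0.154, range from -0.444).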

Other observations

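The comparison of females with males over all 8 mice, treatments weighted equally, and the tests in this part were chosen after the data were seen. Limma called 14 genes, 2 higher and 12 lower in females, with 1426 at an unadjusted p under 0.05 (722 to 2942 without each mouse in turn). Cox8b, a cytochrome oxidase subunit of muscle and brown fat, had a log2 difference of 1.95 (1.53 to 2.36, adjusted p = 0.0118) and Sfrp4 one of 1.62 (adjusted p = 0.0118). Lower in females were Sult1e1 (at least 12-fold), the decoy receptor gene Il1r2 (-2.18, adjusted p = 0.0225), the deiminase gene Padi2 (-1.51, adjusted p = 0.0225) and the hormone-responsive gene Greb1 (-1.46, adjusted p = 0.0320). The count of called genes was 94 without female saline mouse 1 and 36 without female saline mouse 2, or 144 and 27 with lost spots left out as well. It was 7 without male saline mouse 1, 9 without male ketamine mouse 1 and 8 without either female ketamine mouse.

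Adipocyte markers stood higher in females over all 8 mice, with 11 of 11 positive and a median of 0.30 (adjusted p = 0.00203; adjusted p = 0.812 with an estimated correlation), and Pck1 had 2.94 (2.01 to 3.86). The call ended without male ketamine mouse 2 (0.19) or female saline mouse 1 (0.21). By fry 8 lists changed in either direction, and camera called none of them. Basal and squamous epithelium genes (adjusted p = 7.73e-04; camera adjusted p = 0.664) had the hemidesmosome collagen gene Col17a1 at -1.39 (-1.97 to -0.80), Krt14 at -1.03 (-1.53 to -0.53) and Krt6a at 0.70. Fry gave an adjusted p = 6.54e-04 for extracellular matrix (camera adjusted p = 0.0825), with the protease inhibitor gene Timp1 at -0.75 (-1.02 to -0.48), and an adjusted p = 1.27e-04 for inflammatory cytokines (camera adjusted p = 0.106), with the alarmin gene Il33 at -1.15 (-1.63 to -0.68). Immediate early and heat shock genes had an adjusted p = 2.60e-05 (camera adjusted p = 0.896), with Hspa1b at 0.99 and Hspa1a at 1.20. The other 4 were sex-linked genes (adjusted p = 4.10e-06; camera adjusted p = 0.0825), oxidative stress defence (adjusted p = 2.35e-04; camera adjusted p = 0.422), glycolysis and hypoxia (adjusted p = 0.00248; camera adjusted p = 0.637) and glutamate receptors and other ketamine targets (adjusted p = 0.0239; camera adjusted p = 0.506).

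Single spots were lost on some arrays. With a gap of 4 log2 units between the arrays of a mouse, 273 spots were lost, 8 to 39 per array, which touched 68 tested genes. Krt8, a keratin of umbrella cells, was lost on 1 array of male ketamine mouse 1 and 1 array of female ketamine mouse 1, and its log2 change over both sexes was -3.53 (-7.83 to 0.77).

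Among 1485 probes without a gene name, 0 passed in limma in the ketamine contrasts, with 39, 74, 47 and 75 at an unadjusted p under 0.05 in males, in females, over both sexes and for the difference, and 2 passed for sex in saline mice. With every probe tested, another probe of Banf2, a paralog of a nuclear envelope factor, passed in females (adjusted p = 0.00302), at 6.45 and 6.8 in the ketamine females and at background (-0.03 and 0.66) in the saline females. A probe of Mup20, a major urinary protein, passed for sex in saline mice (adjusted p = 0.0146), at 7.32 and 6.12 in females and below the dim level of 5.99 (1.97 and 1.59) in males, so no fold is given for either. These genes were chosen after their values were seen.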
